A study of Homo sapiens with 24 samples.

How the data were processed

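The series measured N6-methyladenosine (m6A) in mRNA by immunoprecipitating fragmented poly(A) RNA with an anti-m6A antibody and sequencing it beside unprecipitated input RNA. Per the labels, 4 stable lines of HepG2, an established liver cancer cell line, were made with lentiviruses that carried either EGFP or METTL14 in its wild-type form (WT) or with the substitution R298P or D312A, and 3 biological replicates of each line gave 24 samples, 12 immunoprecipitated and 12 input. Groups and replicate numbers were taken from the sample titles.

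The authors deposited 1 list of peak summits for each immunoprecipitated library and 1 table for the input libraries of WT and R298P. Per the submitters' processing notes, the tools named were FastQC 0.11.2, Trim Galore 0.4.4, STAR 2.7.9a, Picard, MACS2 2.1.2, HOMER 4.9, bedtools 2.17.0, featureCounts and edgeR, with the genome build hg38; their roles, settings and order are not given in the sources used here. Each summit in the deposited lists carries a value that was read as a −log10 p or q value of MACS2, from its range; which of these it is, which input library each list was called against and the threshold are not given in the sources used here. Per the lists themselves, summits were called for each library and not on pooled libraries, and the lowest value of each list lay between 5.0 and 5.026. The number of reads behind each list is not given in the sources used here, so the depth is unknown and no counting interval could be set. The summit value was used to rank or filter summits within a list and was not compared between lists.

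The authors' deposited table holds a log2 fold change, a mean log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value for each of 42677 genes, per the file headers. All 42677 deposited p-values followed from the likelihood ratio score with 1 degree of freedom, and all 42677 adjusted p-values from Benjamini-Hochberg adjustment, within a set margin. The margin was 0.1% of each value plus a small fixed amount, which left the smallest values in effect unchecked. The header names WT and R298P without saying which of them is the numerator, so signs are given without a direction. The table identifies genes by Ensembl identifiers; 0 of them could be paired with a symbol through the reference table used here. The 18 columns of values per library carry codes that no label ties to a sample, and they were not used. Tests of expression planned on such columns, and with them the gene list tests on expression, enrichment per gene and the expression of genes with changed regions, were therefore not run.

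Summit positions are given 1-based on hg38. Summits of all 12 lists were merged into regions wherever neighbouring summits lay within 100 nt. A region was counted as present in a library with at least 1 summit there. A region was called gained in line A against line B when it was present in 3 of 3 libraries of A and 0 of 3 of B, and lost in the opposite case. With 3 libraries against 3 no single region can pass a test, so counts of regions were set beside all 10 splits of the same 6 libraries, and beside the 10% of regions found in exactly 3 of 6 libraries that would fall wholly into 1 line by chance. Because lists of different length hold different numbers of summits, each count was repeated with every list reduced to its 8669 best summits, the length of the shortest list; this alternative was chosen after the data were examined.

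A summit or region was named after the only protein-coding gene of RefSeq (GRCh38.p14) whose span holds it, or else the only lncRNA gene; 5.91% of summits lay in the spans of several genes and stayed unnamed, so a list member counts as holding a summit only where the summit was assigned to it alone. METTL3, WTAP and the other genes examined by name were counted over their whole span. Spans do not tell exons, introns or untranslated regions apart, and the lists carry no strand, so an overlapping antisense gene cannot be excluded. A genome sequence and exon annotation were not used here, so the planned analyses of sequence motifs, 5-mers, 3′ untranslated regions and stop codons were not run.

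Differences in summit number between 2 lines were tested with two-sided exact permutation tests over the 20 assignments of 3 and 3 libraries, whose smallest p is 0.1. The share of variance between the 4 lines and the sharing of summits within lines were tested over all 15400 partitions of the 12 libraries into 4 groups of 3, and single lines against the other 9 libraries over all 220 choices of 3 libraries; sharing was also tested over the 576 partitions and 64 choices that keep 1 library per replicate number in each group, which was chosen after the data were examined. Sharing was the percent of summits of one library with a summit of another within 100 nt, averaged over both directions. For 33 gene lists fixed before the data were examined, genes with gained or lost regions were tested with Fisher's exact test against 2178 genes with a region in exactly 3 of the 6 libraries, and the list's percent of all summits was tested over the 220 choices; both tests were chosen after the data were examined, in place of the planned tests on expression. Benjamini-Hochberg adjustment was made over the 33 lists.

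Summit positions within regions holding exactly 1 summit in each of the 12 libraries were compared with limma 3.58.1 (lmFit and robust eBayes), 3 libraries against 9, with Benjamini-Hochberg adjustment over 3304 regions, a threshold of 0.05 and a least shift of 20 nt. The comparison of positions and its settings were chosen after the data were examined: a first fit on the same positions used 3164 regions whose positions had an SD over 2 nt, the ordinary eBayes of limma and no least shift, and the robust fit and the least shift were set after its calls had been seen. A limma fit of log2 summits per gene (plus 1) in 4372 genes with a mean of at least 1 summit was also tried at that point. The calls of shifts were tested on simulated data. In 3304 simulated positions, shifts of 20, 30, 50 and 100 nt in R298P were recovered in 44%, 76%, 80% and 88% of 50 regions each, with 11 false calls and 0 calls when nothing was planted. The simulation shuffled the deviations from the line means over the libraries, region by region, which removes any structure that libraries share. Its false calls therefore do not stand for those in the real lists, where a split of EGFP, R298P and D312A of replicate 1 called 27 regions.

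The rule for named items took, for R298P against WT, the 5 gained and 5 lost regions with the best median rank of summit value over the 3 libraries that hold them (gene spans stood in for exons), the regions of METTL14, MALAT1, MYC and SOCS2, the writer genes METTL3 and WTAP, and up to 4 members of each list. Genes outside this rule are named as chosen after their values were seen. The rule, the lists, the merging distance and most of the other settings tried were fixed before the data were examined. These settings were a merging distance of 50 or 200 nt, the 5000 best summits of each list, a summit value of at least 10, presence in at least 2 of 3 libraries, the replicate number as a block, and each library left out. The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.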

Results

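METTL14 is the partner subunit of METTL3, the enzyme that writes m6A into mRNA, and HepG2 is an established liver cancer cell line. The study expressed EGFP as a control, METTL14 (WT), or METTL14 carrying the substitution R298P or D312A in HepG2, and mapped m6A in 3 biological replicates of each line. The 12 deposited summit lists held 155075 summits, from 8669 in D312A replicate 2 to 15373 in EGFP replicate 1, and 10479 genes held at least 1 summit. Between 89.25% and 92.5% of the summits of a library lay in the spans of protein-coding genes. Merging gave 34313 regions, of which 3401 were present in all 12 libraries and 12283 in 1 library. The number of reads behind the lists is unknown. Names of the deposited lists set replicate 1 of all 4 lines apart from replicates 2 and 3, and values within these parts are given below for the comparisons of regions.

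METTL14 itself, examined first because it was the expressed gene, separated the control from the other lines. In each EGFP library its span (hg38, chromosome 4, 118685392 to 118715430) held 1 summit, between positions 118710087 and 118710424 near the 3′ end of the span. It held 9.0 ± 2.0 summits in WT, 8.33 ± 2.08 in R298P and 7.0 ± 3.46 in D312A (SD, n = 3 each), with at least 3 in every library. The difference of EGFP minus the mean of the other 9 libraries was -7.11 summits, and no other choice of 3 of the 12 libraries gave as large a difference (exact permutation test, two-sided, p = 0.0045, the smallest that 220 choices can give). Regions starting at 118687993, 118689436 and 118692042 were present in all 9 METTL14-expressing libraries and in 0 EGFP libraries. These counts do not tell more methylation of METTL14 RNA from more METTL14 RNA made from the construct, since its amount in the input libraries was not examined. METTL3 held 0.667 ± 0.577 summits in EGFP, 1.0 ± 0 in WT, 1.0 ± 1.0 in R298P and 0.333 ± 0.577 in D312A, and WTAP, a further writer subunit, held between 3.0 and 3.67 on average in each line (SD, n = 3); neither differed in summit number in the exact permutation tests of single lines (lowest p = 0.3). A region in the WTAP span that also lies in the span of another gene (chromosome 6, 159755521 to 159755545) was present in 3 of 3 R298P and 0 of 9 other libraries, but was not called with summits merged within 200 nt.

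**Figure D1:**
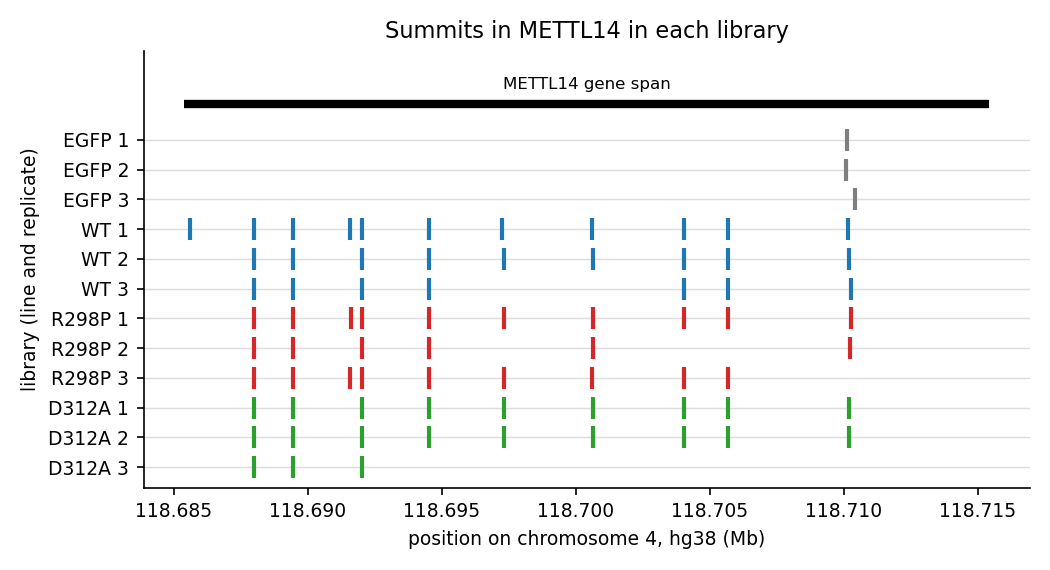
Summits in the METTL14 span for each of the 12 libraries (rows: line and replicate) against position on chromosome 4 of hg38 in Mb; each tick is 1 summit and the black bar is the gene span. The EGFP libraries hold 1 summit each, and the libraries expressing METTL14 hold between 3 and 11.

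R298P against WT asked whether the substitution changes which sites are methylated. Among regions gained in R298P, the best ranked lay in TEX2 (chromosome 17, 64212713 to 64212715), in SNRNP35, a protein of the minor spliceosome (chromosome 12, 123465921 to 123465954), in FEM1B, a substrate receptor of a ubiquitin ligase (chromosome 15, 68290944 to 68290948), in NCOA5, a nuclear receptor coregulator (chromosome 20, 46061734 to 46061744), and in PTCHD4 (chromosome 6, 47878713 to 47878724). Each was present in 3 of 3 R298P and 0 of 3 WT libraries. The TEX2 and NCOA5 regions were absent from all 9 other libraries, while the SNRNP35 region was also present in 2 EGFP and 3 D312A libraries. Among regions lost, the best ranked again lay in SNRNP35 (123466129 to 123466136) and FEM1B (68291081 to 68291196), and further in TBC1D16, a Rab GTPase-activating protein (chromosome 17, 79939827 to 79939842), TF, which encodes transferrin (chromosome 3, 133762312 to 133762325), and CCR6, a chemokine receptor (chromosome 6, 167136628 to 167136656). The lost regions of FEM1B, TBC1D16 and CCR6 were present in all 9 libraries of the other lines and in 0 of 3 R298P libraries. These calls hold for summits merged within 100 nt. With merging within 200 nt, these 5 gained regions and the lost regions of SNRNP35, FEM1B and TBC1D16 joined summits of the other line and were not called, while those of TF and CCR6 were.

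In all, 196 regions were gained and 475 lost in R298P against WT. The gained regions that could be assigned to 1 gene lay in 169 genes and the lost ones in 412. Together the 671 regions were 22.8% of the 2946 regions found in exactly 3 of these 6 libraries, where chance gives 10%. Of the 10 splits of the 6 libraries, the split by line gave the highest count, and the next gave 401; 10 splits cannot give a share under 0.05. In replicates 2 and 3 alone, 816 regions were present in both R298P and no WT libraries and 1319 in both WT and no R298P libraries. In sum these were 2135 against at most 1192 in the other splits. Such counts, here and in the comparisons below, have only 3 splits in all and cannot give a share under 0.05 either. Replicate 1 holds 1 library per line and gives no such count. The excess of lost regions was absent with lists of equal length, where 263 regions were gained and 264 lost, and reversed with the 5000 best summits of each list, with 173 gained and 111 lost. A loss of sites would shorten lists too, so these settings do not tell shorter lists from lost sites. Of the 196 gained regions 111, and of the 475 lost regions 373, were still called with merging within 200 nt. Among the regions named below, those of RBM15, FOXA2, SPRY2 and SOCS7 and the PPARA region starting at 46239041 were not.

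**Figure D2:**
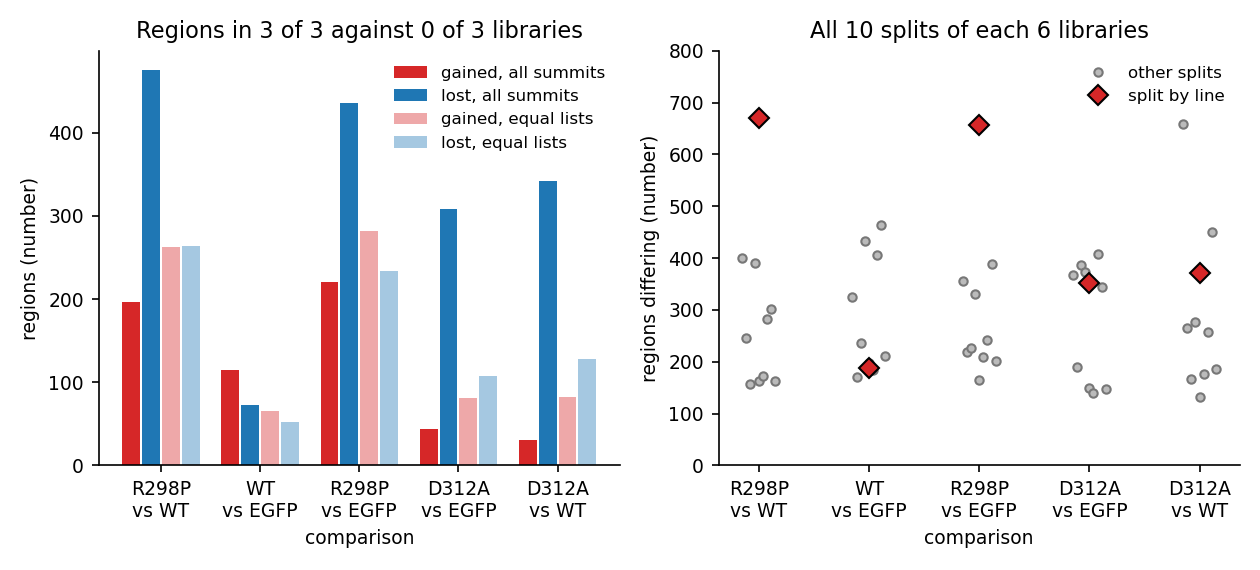
Left, numbers of regions present in 3 of 3 libraries of one line and 0 of 3 of the other for each comparison of lines, with all summits (dark bars) and with lists of equal length (light bars). Right, the number of regions differing in each of the 10 splits of the 6 libraries of a comparison, with the split by line as a diamond: it is the highest for R298P against WT (671) and R298P against EGFP (656).

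Genes of the m6A machinery were among those with changed regions. In the writer complex list, VIRMA, its scaffold subunit, lost a region (chromosome 8, 94488620 to 94488640) that was present in 3 WT and 2 EGFP libraries and in 0 R298P and 0 D312A libraries, and RBM15, an RNA-binding adaptor, gained one (chromosome 1, 110340871 to 110340892). Among the 15 erasers and readers, the readers YTHDF2 (chromosome 1, 28769060 to 28769110) and YTHDC2 (chromosome 5, 113593547 to 113593552) each lost a region and 0 members gained one. YTHDC2 held 1.0 ± 0 summits in WT and 0.0 ± 0 in R298P, whereas YTHDF2 held 3.33 ± 0.577 and 3.0 ± 0 (SD, n = 3). Of the members with a region in exactly 3 of the 6 libraries, 2 of 4 in the writer complex list and 2 of 5 among erasers and readers had a changed region, against 25.7% of the 2178 background genes. The difference did not pass in lists of this size (Fisher's exact test, p = 0.273 and 0.608, adjusted p = 1.0 for both).

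Of 17 liver transcription factors, FOXA2, PPARA and NR1I2 lost regions and 0 gained one. The NR1I2 region was present in 3 WT, 0 EGFP and 0 D312A libraries, so it was not missing in R298P alone. The FOXA2 region was present in 3 EGFP and 2 D312A libraries. PPARA, a nuclear receptor of fatty acid metabolism, lost 2 regions (chromosome 22, 46238115 to 46238127 and 46239041 to 46239066) and held 9.0 ± 2.0 summits in WT and 6.33 ± 2.31 in R298P (SD, n = 3). Its lost regions were present in 1 and 3 EGFP libraries, in this order, and each in 0 D312A libraries. Among the 20 hepatocyte secreted proteins, TF alone lost regions, and its summits numbered 10.0 ± 5.29 in WT and 5.33 ± 3.21 in R298P. In fatty acid synthesis and storage, PLIN2 and PNPLA3, 2 lipid droplet proteins, lost a region and SREBF1, a lipogenic transcription factor, gained one. In bile acid and drug metabolism BAAT lost a region that 1 EGFP and 0 D312A libraries held. UGT2B7, a glucuronosyltransferase, gained one (chromosome 4, 69096515 to 69096536) that no library of another line held. The changed members among those in the background numbered 3 of 9 for liver transcription factors, 1 of 7 for secreted proteins, 3 of 6 for fatty acid synthesis and 2 of 4 for bile acid and drug metabolism, and no list passed (Fisher's exact test, lowest adjusted p over the 33 lists = 1.0).

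Among G2/M cell cycle genes, MKI67 held 7.0 ± 1.0 summits in R298P and 12.3 ± 0.577 in WT, and CENPF, a kinetochore protein, held 1.0 ± 1.0 and 6.0 ± 1.0 (SD, n = 3 each), differences larger than the replicate spread. EGFP libraries held 9.67 ± 0.577 in MKI67 and 3.33 ± 2.08 in CENPF, and D312A libraries 8.67 ± 1.53 and 2.0 ± 1.0 (SD, n = 3), the latter near the R298P value. The 9 genes of this list with summits took 0.104% ± 0.0081 of all summits in R298P and 0.158% ± 0.0089 in WT (SD, n = 3). The list's share was lower in R298P than in the other 9 libraries by an exact permutation test (two-sided, p = 0.0182), which did not pass adjustment over the 33 lists (adjusted p = 0.45). MKI67 and CENPF held most of the summits of this list, so its share follows them and does not speak for the other members. Fatty acid synthesis and storage (lower, exact p = 0.0455) and inflammation and acute phase (higher, exact p = 0.0409) were the other lists under 0.05 before adjustment, and 0 lists passed after it.

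In the immediate early list, SPRY2 and SPRY4, inhibitors of receptor tyrosine kinase signalling, lost regions, and SPRY4 held 5.67 ± 0.577 summits in WT, 3.0 ± 1.0 in R298P, 6.0 ± 1.73 in EGFP and 2.67 ± 0.577 in D312A (SD, n = 3). Of 8 suppressors of cytokine signalling, SOCS1 lost a region (chromosome 16, 11254568 to 11254580) and held 1.33 ± 0.577 summits in WT and 0.0 ± 0 in R298P, and SOCS7 gained one (chromosome 17, 38399852 to 38399865). In each of these lists 2 of the 4 members in the background had a changed region (Fisher's exact test, p = 0.273, adjusted p = 1.0). SOCS2 held 0.333 ± 0.577 summits in WT and 1.0 ± 1.0 in R298P, with no region gained or lost. MYC, in 3 of the lists, held 2.0 ± 0 and 1.0 ± 1.0, and its region at 127740610 to 127740623 on chromosome 8 was present in 3 WT, 2 EGFP, 1 D312A and 0 R298P libraries. The nuclear RNA MALAT1 held 2.0 ± 1.73 and 1.33 ± 0.577. None of MYC, SOCS2 and MALAT1 differed between R298P and the other 9 libraries in summit number (exact permutation tests, lowest p = 0.21).

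Among glycolysis genes 12 of 20 members were assigned summits, 6 held a region in exactly 3 of the 6 libraries, and 0 had a gained or lost region (Fisher's exact test, p = 0.348). For other lists without a changed gene such a count could hardly differ from 0: members with a region in exactly 3 of the 6 libraries numbered 2 for interferon response (10 of 29 with summits), 1 for p53 targets (16 of 20), 1 for fatty acid oxidation (8 of 18), 0 for G1/S genes (13 of 20) and 0 for metallothioneins (7 of 10). Markers of other cell types were scarce, with summits in 1 of 13 fibroblast and stellate cell markers, 4 of 13 blood and macrophage markers and 2 of 9 endothelial markers. The mitochondrial genome held between 0 and 33 summits per library, with no pattern common to the lines: WT and R298P held 33 and 31 in replicate 1 and 2 or 3 in their other replicates, D312A held 25, 31 and 1 in replicates 1, 2 and 3, and EGFP held 8, 0 and 16.

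WT against EGFP asked what added METTL14 changes. METTL14 held the summits described above, while VIRMA held 3.33 ± 1.53 summits in WT and 3.0 ± 1.0 in EGFP, and MYC 2.0 ± 0 and 2.0 ± 1.0 (SD, n = 3). Across all regions, 115 were gained and 72 lost. These 187 were 6.65% of 2810 regions in exactly 3 of the 6 libraries, below the 10% of chance, and the highest of the other splits gave 464. In replicates 2 and 3 alone, 717 were gained and 480 lost, and 1 of the other splits gave more, with 1319.

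R298P against EGFP gave counts close to those against WT. With merging within 100 nt, the TEX2 and NCOA5 regions were gained and the FEM1B, TBC1D16 and CCR6 regions lost here too, since EGFP libraries matched WT at these 5 places. In all, 220 regions were gained and 436 lost, in sum 656 or 21.9% of 2992 regions in exactly 3 of 6, and the highest of the other splits gave 388. The excess of lost regions reversed with lists of equal length (282 gained, 234 lost) and with the 5000 best summits (189 and 137). In replicates 2 and 3 alone, 967 were gained and 1115 lost, in sum 2082 against at most 1101 in the other splits.

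D312A was compared with EGFP and with WT. SPRY4 and VIRMA held fewer summits in D312A than in either on average, with 1.0 ± 0 in VIRMA against 3.33 ± 1.53 in WT, and PPARA held 4.0 ± 2.65 against 9.0 ± 2.0 (SD, n = 3). Against EGFP 44 regions were gained and 308 lost, and against WT 30 were gained and 342 lost. These made up 12.3% and 12.7% of the regions in exactly 3 of 6 libraries. Other splits of the same libraries gave up to 408 regions against the 352 of D312A and EGFP, and up to 659 against the 372 of D312A and WT. D312A had the shortest lists on average, and with lists of equal length 81 regions were gained and 108 lost against EGFP, and 82 and 128 against WT. In replicates 2 and 3 alone 261 regions were gained and 1161 lost against EGFP, in sum 1422 where another split gave 1582, and 218 and 1459 against WT, in sum 1677 where the other splits gave at most 1413.

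The number of summits per library was 13966 ± 1360 in EGFP, 14177 ± 1360 in WT, 12424 ± 1140 in R298P and 11125 ± 2130 in D312A (SD, n = 3 each). Lines accounted for 49.2% of the variance among the 12 libraries (exact permutation test over all partitions into lines, p = 0.116). The mean of R298P minus that of WT was -1753 summits, with R298P shorter in all 3 replicate numbers (exact permutation test, two-sided, p = 0.2). It was -2837 in replicate 1 and -1211.5 in replicates 2 and 3. D312A minus EGFP was -2840 and D312A minus WT was -3052 (exact p = 0.1 for both, the smallest that 20 assignments allow), with -3016 and -2440 in replicate 1 and -2752.5 and -3357.5 in replicates 2 and 3. Without D312A replicate 2, the shortest list, they were -1612 and -1824 (exact p = 0.2 for both). R298P minus EGFP was -1542 (exact p = 0.2), with -3413 in replicate 1 and -606.5 in replicates 2 and 3, and -838.3 without EGFP replicate 1 (exact p = 0.4). WT minus EGFP was 211.3 (exact p = 1.0), and its sign differed between replicate 1, with -576, and replicates 2 and 3, with 605.0. Counting only summits with a value of at least 10 raised the share of variance between lines to 61.5% and its exact p fell below the threshold, to 0.0417.

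**Figure D3:**
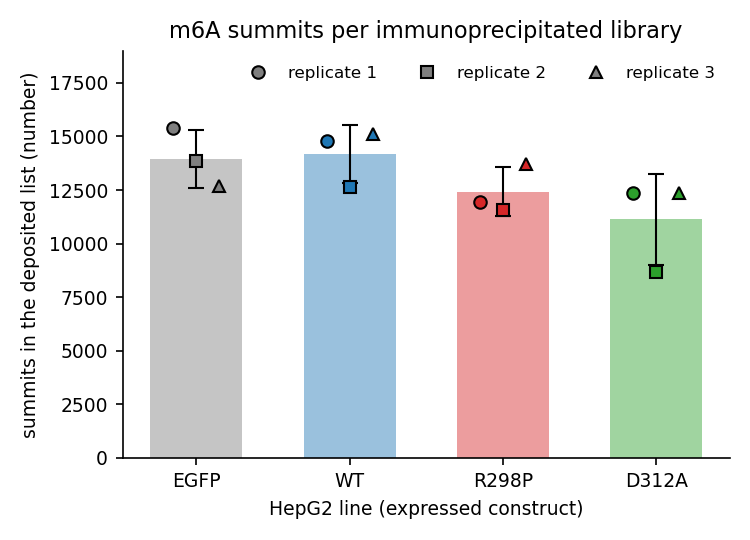
Number of summits in the deposited list of each immunoprecipitated library by line; bars are means of 3 libraries, error bars are SD and symbols are single libraries. D312A replicate 2 has the shortest list, with 8669 summits, and EGFP replicate 1 the longest, with 15373.

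Libraries of the same line shared 63.0% of their summits (SD 2.19 over 12 pairs) and libraries of different lines 61.9% (SD 3.5 over 54 pairs), a difference of 1.095 percentage points (exact permutation test, p = 0.11 over all partitions and 0.0191 over those within replicate numbers). Pairs that joined R298P with another line shared 60.0% (SD 2.57 over 27 pairs), and pairs between EGFP, WT and D312A shared 63.8% (SD 3.3 over 27 pairs). R298P libraries shared 62.2% of summits with each other (SD 1.49 over 3 pairs), which exceeded their sharing with other lines by 2.199 points (exact permutation test, p = 0.114 over 220 choices and 0.0469 over the 64 choices within replicate numbers). The excess was similar among WT libraries, at 2.035 points (exact permutation tests, p = 0.127 and 0.0625). With lists of equal length it was 3.044 points in R298P (exact permutation tests, p = 0.0636 and 0.0156) and 2.482 points in WT (p = 0.109 and 0.0469). Libraries of different lines shared 63.9% where they carried the same replicate number (SD 3.75 over 18 pairs) and 61.0% where they did not (SD 2.97 over 36 pairs). The differences for all lines and for R298P passed 0.05 only where the replicate number was held fixed. That for WT passed only there and with lists of equal length.

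Expression of WT and R298P input libraries was read from the authors' deposited table, which lists 1168 of 42677 genes at an adjusted p under 0.05, or 2.74%. Of these genes, 636 have a positive and 532 a negative log2 fold change in the authors' deposited table, with a median absolute value of 0.603, and 269 reach an absolute value of 1. Among those of these genes with a mean log2 CPM of at least 1, the authors' deposited table gives its highest log2 fold change to ENSG00000148702.14 (4.81, adjusted p = 1.8e-46), and its lowest to ENSG00000184985.16 (-2.04, adjusted p = 3.6e-15). The sign is not tied to WT or R298P in the table, and these genes could not be matched to the symbols of the summit regions.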

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

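Settings fixed before the data were examined were the merging distance, the 5000 best summits, the least summit value of 10, presence in at least 2 of 3 libraries and, for summits per library, the replicate block and the omission of single libraries; lists of equal length, the omission of libraries for regions, the block for sharing, and every setting for summit shifts, for regions of R298P alone, for regions differing between lines and for the authors' table were chosen after the data were examined. The share of variance in summits per library between lines was 61.46% with summit values of at least 10 (exact permutation p = 0.0417). The difference WT minus EGFP took the opposite sign without WT replicate 1 (-98.67), WT replicate 3 (-257.2) or EGFP replicate 3 (-439.0), within a range up to 989.8 over single omissions; the cause was not tested. Over single omissions R298P minus EGFP lay between -2192 and -838.3, D312A minus EGFP between -3491 and -1612 and D312A minus WT between -3830 and -1824. Replicate numbers did not meet the rule for pairing, since correlations of deviations between libraries of the same number ranged from -0.00342 to 0.179 (mean 0.145 in replicate 1, 0.0376 in replicate 2 and 0.0437 in replicate 3). Between libraries of different lines and numbers they ranged from -0.151 to 0.0827 (mean -0.0377). All pairs of replicate 1 lay above that range (0.0871 to 0.179), while the ranges of replicates 2 and 3 overlapped it. With the replicate block, the difference in sharing of 1.095 points had an exact permutation p of 0.0191 and the sharing among R298P libraries an exact p of 0.0469. For summits per library, the share of variance between lines had an exact permutation p of 0.0885 with the block. The tests of 2 lines with the block have 8 sign flips, whose smallest p is 0.25, so none of them could pass the threshold. For summit shifts in R298P the block gave 20 calls. Counts of regions follow from how strict the rule is. With the 5000 best summits, 284 regions differed between R298P and WT (173 gained and 111 lost, the reverse of the main balance), 82 between WT and EGFP (40 and 42, also reversed), 326 between R298P and EGFP (189 and 137, also reversed), 87 between D312A and EGFP and 96 between D312A and WT. With presence in at least 2 of 3 libraries against none these counts were 2793 (976 gained, 1817 lost), 1505, 2902, 1977 and 1905, and 435 regions of R298P alone. With lists of equal length 264 regions were lost in R298P against WT, 117 differed between WT and EGFP, 189 between D312A and EGFP and 210 between D312A and WT, and 111 were of R298P alone. Merging at 200 nt gave 113 regions gained in R298P against WT and 40 of R298P alone; 111 of the 196 gained, 373 of the 475 lost and 39 of the 71 regions of R298P alone were still called then, and all 5 gained regions named first in R298P against WT were not, because they joined summits of WT. Omitting single libraries asks for 2 of 2 in place of 3 of 3 and so raised counts: to between 1098 and 1423 for R298P and WT (gained 283 to 490, lost 695 to 1005), 448 to 605 for WT and EGFP, 1135 to 1378 for R298P and EGFP, 622 to 942 for D312A and EGFP, 640 to 938 for D312A and WT, and 74 to 208 for R298P alone, where the libraries with a move over 1.5 times were the R298P ones (205, 208 and 164). In the differing counts each of the 6 libraries moved the count by over 1.5 times. Shifts in R298P numbered 9 with merging at 50 nt, 5 with summit values of at least 10, 50 in replicates 2 and 3 alone, and 34 and 25 without R298P replicate 1 or 2. The count of genes in the authors' table was 1540 at an adjusted p of 0.1 and 1390 with the adjustment over genes of a mean log2 CPM of at least 1. Not run were all results on sequence motifs, 5-mers, 3′ untranslated regions and stop codons, enrichment per gene, and every other setting for expression and its gene lists, including the block and single omissions.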

Other observations

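The counts of regions gained and lost in R298P against WT were set beforehand. So were merging within 200 nt and the 5000 best summits of each list, as other settings for these counts. All tests beyond these counts in this part were chosen after the data were examined. Those against other splits were chosen after the counts of regions, shifts and genes had been seen.

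R298P libraries held regions that no other library held, and the genes named here were chosen after their values were seen. Beside TEX2 and NCOA5, regions present in 3 of 3 R298P and 0 of 9 other libraries lay in HARBI1 (chromosome 11, 46615803 to 46615804), in TAF5L, a subunit of histone acetyltransferase complexes (chromosome 1, 229594923 to 229594926), in BCL9L, a cofactor of beta-catenin (chromosome 11, 118902088 to 118902115), and in KANSL3, a subunit of another histone acetyltransferase complex (chromosome 2, 96593539 to 96593542). The liver enzyme gene UGT2B7 and the transcription factor gene TBX3 (chromosome 12, 114671675 to 114671695) also had such a region. There were 71 regions of this kind, 61 of them in 61 genes, against 26 regions in WT alone, 11 in EGFP alone and 0 in D312A alone. In the opposite direction, 23 regions were present in all 9 other libraries and in no R298P library, in TRAF6, MARK2, LTBR, MLX, FBXO28 and F2RL1 among others, where the sets of 9 libraries without EGFP, WT or D312A gave 7, 1 and 9. Other splits came close or gave more: 5 of all 220 gave as many (highest other 50), and with 1 library per replicate number the next gave 22, or 17 against 20 for R298P with lists of equal length. With merging within 200 nt, 14 regions were missing in R298P alone and 5 of the 64 splits with 1 library per replicate number gave as many, so this count was not set apart from other splits there. Of the regions named here, those of TEX2, NCOA5, HARBI1, TAF5L, BCL9L, KANSL3, TRAF6, LTBR, FBXO28 and F2RL1 were not called with merging within 200 nt, and those of UGT2B7, TBX3, MARK2 and MLX were.

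Some gained and lost regions lay side by side in R298P. In FEM1B and SNRNP35 the gained and the lost region lay 133 and 175 nt apart in the same gene. TAF5L held its R298P region at 229594923 and a region at 229594775 to 229594793 that all 9 other libraries held and R298P lacked, 130 nt away. With merging within 200 nt each of these pairs was 1 region held by both lines, and the gained and lost calls ended. Of the 196 regions gained against WT, 18 had a lost region within 500 nt, or 9.18%, and the other splits of these 6 libraries gave at most 6 regions and 5.77%. The split by line also offered more regions to lie near, 475 lost ones against at most 251 in the other splits. These shares do not allow for that, so an excess of regions side by side was not shown. For 15 of the 18 the gained and a lost region were 1 region with merging within 200 nt. At that distance 3 of the 113 gained regions had a lost region near (2.65%), and the other splits gave up to 1 region and 2.86%. The share thus also depends on the merging distance.

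Summits also moved within regions present in all 12 libraries. In R298P the summit lay 103 nt from its mean place in the other 9 libraries in FBXO31, a ubiquitin ligase subunit (SE 2.56, limma adjusted p = 3.9e-10), -94.1 nt in DUSP16, a MAP kinase phosphatase (SE 2.57, adjusted p = 5.7e-10), -90.9 nt in DCBLD2 (SE 2.57, adjusted p = 5.7e-10) and 89.1 nt in EP300, a histone acetyltransferase (SE 3.64, adjusted p = 2.1e-08), each with 3 R298P and 9 other libraries and with no overlap of their ranges. Smaller shifts were called in DST (-54.2 nt), ING5 (-64.0 nt), STRBP (-65.6 nt) and RPS6KA3 (-32.7 nt). The regions of FBXO31, EP300 and RPS6KA3 held more than 1 summit in some library with merging within 200 nt, so that adjacent summits stay open for them. Those of the other genes named here held 1 in each. That does not exclude adjacent summits of which each library called only 1. These calls depend on settings chosen after a first fit of the same positions had been seen. Of 3304 regions tested with limma, 16 were shifted in R298P, 2 in EGFP, 1 in D312A and 0 in WT. The count in R298P was 9 with merging within 50 nt, 5 with summit values of at least 10, and 34 and 25 without R298P replicate 1 or 2. At an unadjusted p under 0.05 and the same least shift the counts were 150, 42, 46 and 32.

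For the 71 regions of R298P alone, the 220 splits of the 12 libraries into 3 and 9 gave as many in 2 cases, R298P included. The other one was EGFP, WT and D312A of replicate 1 with 103, which points to a structure shared by replicate 1. With 1 library per replicate number in a split, 1 of 64 gave as many, R298P itself, and the highest other gave 32. Both shares are under 0.05. The splits were chosen after the counts had been seen, however, and a split that follows no line gave more. Chance is thus argued against but not excluded. The first replicate number as a batch was argued against but not excluded. Within replicates 2 and 3 alone, the R298P pair held 364 regions of its own, and the highest of the other 27 pairs 296. The 71 regions are by definition among the 364, and 1 of 28 choices is the smallest share possible. With lists of equal length the R298P pair held 332 and the highest other pair 145. List length was excluded, since with such lists the 3 R298P libraries held 111 regions. The other splits with 1 library per replicate number held at most 13, so 1 of the 64 gave as many. The summits lay at a median percentile of 49.9 in their own lists, which did not decide whether they were near the calling threshold, but for summits among the 5000 best of each list R298P had 12 regions absent from the other 9 full lists, against at most 4 in the other splits, and at the other regions of the same genes the share of libraries with a summit differed by -2.19 percentage points, R298P minus the other lines (95% interval -6.14 to 1.68), which argues against higher RNA abundance of the host genes. Adjacent summits parted by the merging distance were argued against as the whole cause, since with merging within 200 nt R298P held 40 regions of its own and 1 of the 64 splits with 1 library per replicate number gave as many (highest other 27), while 6 of the 220 did (highest other 82, again EGFP, WT and D312A of replicate 1); but 39 of the 71 were still called, and for the others a shift of a summit by a short distance stays open. A candidate explanation that stays open is that R298P lays m6A at other sites than WT METTL14, which no test here decides: sequence motifs at these regions were not examined, and each construct is 1 stable line, so the substitution and other differences between lines were not separated.

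The excess of lost over gained regions in R298P against WT (475 and 196) was not separated from list length: the ratio of lost to gained regions was 1.0 with lists of equal length and 0.642 with the 5000 best summits of each list (111 lost, 173 gained). The excess thus did not hold among the best summits, but a loss of sites would itself shorten lists. For lower RNA abundance of the host genes, the other regions of genes with lost regions were compared (363 of the 412 had any). Their presence differed by -3.62 percentage points, R298P minus WT (95% interval -5.29 to -1.86). This was short of the 10 points set beforehand, but the whole interval was negative, the direction that lower abundance would give. Shorter lists would give that direction too, with 12424 summits on average in R298P and 14177 in WT. No value over all genes was set beside the difference, so its sign does not tell abundance from list length. Expression could not be matched to these genes, so lower abundance was not decided and stays open. A difference in depth, which may set list length, stays open because the depth is unknown, and so does a loss of m6A sites in R298P, which was not tested.

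For the 16 shifted regions of R298P, 2 of 100 drawn splits of the 12 libraries into 3 and 9 gave as many, R298P included. The other was a split of 3 replicate 1 libraries with 27 shifts. Under the settings tried first, R298P had 23 shifts and again 2 of the 100 splits gave as many (highest other 36), and 1 of 64 within replicate numbers (highest other 2). Under the final settings 1 of 64 splits within replicate numbers gave as many and the highest other gave 2. These shares are under 0.05. The test and its settings were chosen after calls had been seen, however, and a split that follows no line gave more. Chance is thus argued against but not excluded. The first replicate number as a batch was excluded as the whole cause, since a fit of replicates 2 and 3 alone called 50 regions for the R298P pair, 14 of the 16 among them, and 1 of the 28 choices of 2 of these 8 libraries gave as many, R298P itself (highest other 11). Adjacent summits inside wide merged regions stay open, since only a share of 0.625 held exactly 1 summit in every library when merged at 200 nt. For that share too, adjacent summits of which each library called only 1 were not excluded. A change of the methylated site within the transcript may give such shifts, and so could a shift of fragment ends or of isoform, which were not tested; each construct is 1 stable line here too.

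The other comparisons gave less. For regions of 1 line alone, 96, 19 and 220 of the 220 splits gave as many as EGFP (11), WT (26) and D312A (0), so chance cannot be excluded for these by all splits. With 1 library per replicate number, 20, 3 and 64 of 64 did (highest other 71, R298P itself); for WT that share is under 0.05, but with lists of equal length WT held 10 regions of its own and 8 of the 64 gave as many, so the WT count depends on which splits are counted and on list length. For summit shifts, 20, 100 and 43 of 100 drawn splits gave as many as EGFP (2), WT (0) and D312A (1; highest other 27), and 4, 64 and 18 of the 64 within replicate numbers did (highest other 16, R298P), so chance cannot be excluded there either. For regions differing between 2 lines, 10 splits are too few for a share under 0.05: 1 split gave as many as R298P against WT (671, highest other 401) and 1 as many as R298P against EGFP (656, highest other 388), while 8, 5 and 3 splits gave as many as WT against EGFP (187, highest other 464), D312A against EGFP (352, highest other 408) and D312A against WT (372, highest other 659). In each of these comparisons the highest other split had both replicate 1 libraries on one side: EGFP 1, EGFP 3 and WT 1 for WT against EGFP, EGFP 1, EGFP 2 and D312A 1 for D312A against EGFP, and D312A 1, D312A 2 and WT 1 for D312A against WT. For summits per gene, tried with limma before the shifts, 6 of 4372 genes were called in R298P against the other 9 libraries, and 6 of 100 drawn splits gave as many (highest other 23), so chance cannot be excluded by these; with 1 library per replicate number 2 of 64 did (highest other 8), a share under 0.05, so the call depends on which splits are counted. For the 5 genes called in D312A, 6 of the 100 and 3 of the 64 gave as many.

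The peak names in the list of R298P replicate 2 carry a version mark on all 11590 summits, and 0 summits do in each of the other lists. Without that library, 208 regions were present in both other R298P libraries and in none of the other 9, and without R298P replicate 1 or 3 the counts were 205 and 164.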
